A study of Homo sapiens with 18 samples.

How the data were processed

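HCT116 is an established human colorectal carcinoma line, and the series compared 9 isogenic clones of it that differ at IDH1 or IDH2, the genes of the cytosolic and the mitochondrial NADP-dependent isocitrate dehydrogenase. Each clone was measured in 2 biological replicates, which gave 18 one-colour Affymetrix expression arrays of 54675 probe sets. Total RNA was taken after 6 days of growth, amplified and labelled with biotin. The clones were the parental line; 16F8, which the labels describe as wild-type at the mRNA level although it was targeted with IDH1 R132C; 2C11 and 2H1 with IDH1 R132H; 3A4 with IDH1 R132C; 8G12 and 17H5 with IDH2 R140Q; and 47C2 and 45G3 with IDH2 R172K. In the titles every targeted clone is heterozygous (/+), and 16F8 is marked as not expressing its mutant allele. Parental and 16F8 formed the wild-type group, and the other 7 clones the mutant group.

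The deposited values are probe set intensities, per the labels MAS5 signals on a linear scale; the version of MAS5 and its settings are not given in the sources used here. The values ran from 0 to 8500.9 with a median of 13.1, and 15.4% of them lay under 1. The mean of the middle 96% of probe sets was 149.98 in every array, so the authors had scaled the arrays to 1 level. Array medians lay between 12.3 and 15.6. Arrays give no counts, and the number of arrays limits the precision: 2 per clone.

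The signals were taken as log2 of the signal plus 2.2, the 25th percentile of all values. Of the probe sets, 41091 carried 1 gene symbol, 1801 carried several and 11721 carried none; 62 were AFFX controls. A probe set was tested when both arrays of at least 1 clone lay at or above the array's median, and each gene was represented by the probe set with the highest mean, which left 12531 of 19775 genes. Linear models were fitted in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with a trend on mean expression), and two-sided p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Genotypes were compared on the 9 clone means, with the clone as the replicate: mutant against wild-type with 7 residual degrees of freedom, IDH1, IDH2 and wild-type groups with 6, and the 5 genotypes with 4. The single R132C clone was assumed to vary like the other genotypes. Each clone was compared with parental on the 18 arrays with 9 residual degrees of freedom; these tests compare clones, not genotypes. Errors of log2 changes are standard errors and errors of signals are standard deviations of 2 arrays, unless stated otherwise.

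An epithelial-mesenchymal transition (EMT) score was the mean log2 of a mesenchymal marker list minus that of an epithelial marker list, compared by an exact two-sided permutation test over the 36 ways to choose 2 of 9 clones, whose smallest p is 0.0278. The exact tests of 3 against 4 mutant clones have 35 splits and a smallest p of 0.0286. Correlations with ZEB1 were tested by enumerating all 362880 orders of the clones. For 23 gene lists of 562 genes, 408 of them tested, limma's camera compared the list with all other genes, with a preset inter-gene correlation of 0.01 and also with an estimated one; fry tested whether the genes of a list moved, on balance, one way. The lists covered epithelial and mesenchymal markers, EMT transcription factors, miR-200 targets, signalling and metabolic pathways, stress responses, the cell cycle, chromatin machinery, and fibroblast and haematopoietic markers as a check for other cells; 26 genes were in more than 1 list. Genes of each chromosome from 1 to 22 and of X were tested in the same way; genes of chromosome Y were in the tests and counts of single genes, and neither their levels nor a test of that chromosome is reported here. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

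The groups, main tests, lists, rule for named genes and main alternatives were chosen before the data were examined. The correlations with ZEB1, the exact tests of single genes and the counts of genes in which a clone lay apart were not part of that plan. Genes are named by this rule: IDH1, IDH2, ZEB1, ZEB2, CDH1, EPCAM, VIM and CDH2 in every clone; for mutant against wild-type clones the 10 highest and 10 lowest changes past the threshold with all 7 clones on 1 side, or else the 10 smallest p-values; for each other genotype comparison the 5 highest and 5 lowest past the threshold, or else up to 3 of the smallest p-values; for each clone against parental the 3 highest and 3 lowest estimates; and up to 4 members of each list described. Genes without an official symbol are not named, and 1 gene that the rule would name is not reported here. The alternatives were other offsets, filters, normalization, probe sets, variance models, replication units, wild-type references, the replicate number as a block, and leaving out each array or clone. An offset of 50, terms for the 4 arrays with high poly-A controls, and 16F8 as the reference for single clones were chosen after seeing the data.

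On simulated data of the same size, with 100 genes changed 2-fold, the models recovered 75% of them for mutant against wild-type clones, 85% for IDH2- against IDH1-mutant clones, 69% for R132H against wild-type clones and 85% for 1 clone against parental; 4-fold changes were recovered in 92%, 97%, 94% and 100%. Of the unchanged genes 10 to 13 were called in a run. Each run held the 100 genes changed 2-fold and 100 changed 4-fold together, with noise drawn independently for each gene. Genes that vary together between clones were not simulated, so these rates are not the power of the real comparisons.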

Results

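The data were 18 expression arrays of 9 HCT116 clones, 2 biological replicates of each, taken to ask how IDH1 and IDH2 mutations relate to the epithelial-mesenchymal transition (EMT), the switch of cells from an epithelial to a mesenchymal programme. The replicate arrays of a clone correlated at 0.9869 (45G3) to 0.9952 (47C2), and arrays of different clones at 0.9505 to 0.9905. The first 2 principal components held 32.4% and 17.5% of the variance. Replicate numbers did not pair the arrays: over 36 pairs of clones the deviations of replicate 1 correlated at -0.351 to 0.385. The spiked poly-A controls were 1.7-fold higher in 4 arrays (parental 1, 2C11 1, 16F8 1 and 8G12 2) than in the other 14, and the deviations of these 4 from their clone means correlated at 0.284 to 0.385.

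IDH1 was abundant in every clone, with signals from 1120 ± 125 (SD, n = 2) in 16F8 to 2190 ± 129 in 2H1 and 1850 ± 223 in parental. It was lower than in parental in 16F8 by a log2 change of -0.72 ± 0.12 (adjusted p = 0.000356), in 8G12 by -0.39 (0.0272), in 47C2 by -0.47 (0.00698) and in 45G3 by -0.41 (0.0153). In 2C11, 2H1, 3A4 and 17H5 it did not pass the test. With the IDH1 probe set of highest variance the changes in 8G12 (-0.28), 47C2 (-0.15) and 45G3 (-0.18) did not pass. With it 16F8 still passed as lower (-0.84), and 2H1 passed as higher (0.94, adjusted p = 0.00824). IDH2 lay at 127 ± 36 in parental and rose in both R140Q clones, by 1.11 ± 0.21 in 8G12 (adjusted p = 0.00125) and 0.85 ± 0.21 in 17H5 (0.0138), but not past the threshold in the R172K clones, with 0.40 in 47C2 and 0.33 in 45G3. With the IDH2 probe set of highest variance it rose in all 8 clones, by 1.49 in 8G12, 1.42 in 17H5, 1.12 in 47C2, 1.03 in 45G3, 0.98 in 16F8, 0.88 in 3A4, 0.68 in 2C11 and 0.52 in 2H1. Against 16F8, a reference chosen after seeing the data, IDH2 passed in 8G12 (1.14, adjusted p = 0.0122) and 17H5 (0.88, 0.0148) alone. IDH1 was higher than in 16F8 in 2C11 (0.72, adjusted p = 0.00193), 2H1 (0.97, 2e-05) and 3A4 (0.48, 0.00647), and the differences in 8G12 (0.33), 47C2 (0.25) and 45G3 (0.31) were positive and did not pass, so its direction depends on the wild-type reference. The arrays do not separate mutant from wild-type transcripts. Per the titles 16F8 carries a mutant IDH1 allele that it does not express, so it is not an equal reference for IDH1 itself. Whether that allele lowers its IDH1 signal was not tested.

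ZEB1, a transcription factor that represses epithelial genes and is itself held down by the miR-200 family, differed widely between the clones. Its signal was 149 ± 5.87 in parental and 109 ± 10.6 in 16F8, against 217 ± 11.5 in 2C11, 407 ± 32.1 in 2H1, 430 ± 18.7 in 3A4, 305 ± 28.1 in 47C2 and 269 ± 53.1 in 45G3. The R140Q clones stayed near parental, at 158 ± 24.7 in 8G12 and 117 ± 1.7 in 17H5. Against parental ZEB1 rose by 0.53 in 2C11 (adjusted p = 0.0128), 1.43 in 2H1 (1.24e-06), 1.51 in 3A4 (7.36e-07), 1.02 in 47C2 (7.75e-05) and 0.83 in 45G3 (0.000469), each ± 0.15. It fell by 0.45 in 16F8 (0.0368), and 8G12 (0.07) and 17H5 (-0.35) did not pass. With the ZEB1 probe set of highest variance, a dim one, no clone passed against parental. It gave 0.97 in 2H1, 1.15 in 3A4, 0.27 in 47C2, 0.37 in 45G3, -0.36 in 2C11 and -1.20 in 16F8.

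CDH1, which encodes E-cadherin, the adhesion molecule of epithelial junctions, fell in the same 5 mutant clones. Its signal of 1560 ± 48.6 in parental compared with 478 ± 22.3 in 2H1, 452 ± 2.47 in 3A4, 520 ± 5.94 in 47C2, 646 ± 125 in 45G3 and 792 ± 192 in 2C11. The log2 changes were -1.70, -1.78, -1.58 and -1.28 in the first 4 of these, and the adjusted p was at most 4.38e-05, the value in 2C11. CDH1 also fell in 16F8, by -0.61 (adjusted p = 0.00424), and in 8G12, by -0.59 (0.00582). VIM, the mesenchymal intermediate filament vimentin, rose in the same 5 clones, by 1.39 in 2H1, 1.39 in 3A4, 1.17 in 47C2, 0.76 in 45G3 and 0.68 in 2C11. It was lower in 16F8 (-0.81, adjusted p = 0.00179) and 17H5 (-0.72, 0.00786). EPCAM, an epithelial surface protein, fell as well, with log2 changes of -0.79 in 2H1, -0.73 in 3A4, -0.49 in 47C2, -0.39 in 45G3 and -0.32 in 2C11. Against 16F8 ZEB1 and VIM passed as higher in the same 5 clones. CDH1 passed as lower there in 4 of them and not in 2C11 (-0.39, adjusted p = 0.183), and had a difference of 0.02 in 8G12. EPCAM passed as lower against 16F8 in 2H1 (-0.55) and 3A4 (-0.49) and not in 2C11 (-0.08), 47C2 (-0.25) or 45G3 (-0.15). ZEB2, a relative of ZEB1, and CDH2, the mesenchymal N-cadherin, were near the background, with signals of 0.5 to 2.9 and 1.85 to 10.9, and were not tested.

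**Figure D1:**
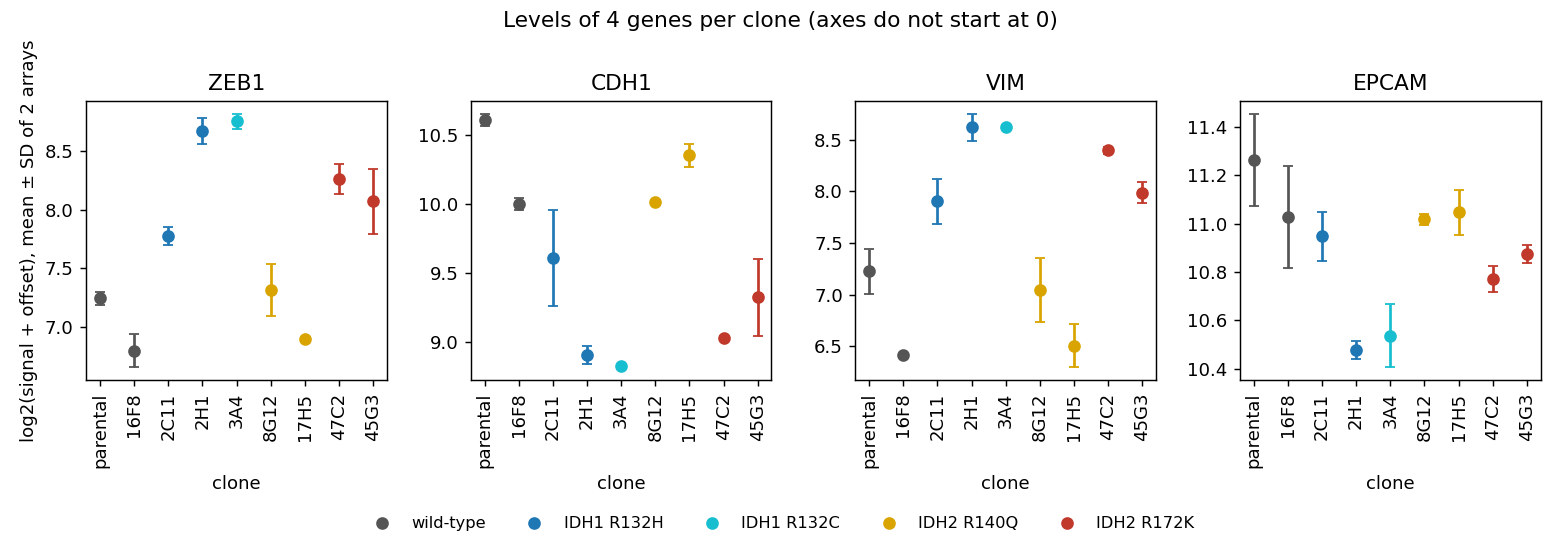
Levels of ZEB1, CDH1, VIM and EPCAM (y axis, log2 of the signal plus 2.2) in the 9 clones (x axis); points are means and error bars the SD of 2 arrays, and the axes do not start at 0. The signals behind them were 407 in 2H1 and 430 in 3A4 against 149 in parental for ZEB1, and 478 and 452 against 1560 for CDH1.

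Across the 9 clone means ZEB1 ran opposite to epithelial genes and with VIM. CDH1 against ZEB1 gave Pearson r = -0.92 (exact permutation p = 0.0013, adjusted 0.0014) and Spearman rho = -0.883 (p = 0.0031, adjusted 0.0045). VIM gave r = 0.983 (p = 2.5e-05, adjusted 9.9e-05) and rho = 0.983 (p = 5e-05, adjusted 0.0002). The mean of the epithelial list gave r = -0.943 (p = 0.00036, adjusted 0.00071) and rho = -0.867 (p = 0.0045). That of the mesenchymal list without ZEB1 gave r = 0.842 (p = 0.0014) and rho = 0.867 (p = 0.0045). The adjustment covered these 4 relations. Without 3A4 and 16F8, the clones farthest from the median of ZEB1, r was -0.948, 0.98, -0.961 and 0.827 in the same order. On the arrays with low poly-A controls alone it was -0.91, 0.989, -0.952 and 0.824, and the 4 other arrays were too few for a value.

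The EMT score, the mesenchymal minus the epithelial list mean on the log2 scale, was -1.29 ± 0.10 (SD of 2 arrays) in parental and -1.29 ± 0.12 in 16F8. It was higher in the R132H clones, at -0.66 ± 0.07 in 2C11 and 0.36 ± 0.01 in 2H1, in the R132C clone 3A4, at 0.02 ± 0.03, and in the R172K clones, at -0.33 ± 0.01 in 47C2 and -0.54 ± 0.19 in 45G3. The R140Q clones lay lowest of the mutants, at -0.95 ± 0.12 in 8G12 and -1.21 ± 0.10 in 17H5. All 7 mutant clones lay above both wild-type clones, by 0.82 in the mean (-0.47 ± 0.54 against -1.29, SD over clones). For 17H5 the gap to parental was 0.08, less than the pooled SD of replicate arrays, 0.0982. The exact permutation test gave p = 0.0833 where 0.0278 was the smallest possible. IDH1-mutant clones (-0.09 ± 0.52) and IDH2-mutant clones (-0.76 ± 0.40) differed by 0.66 (exact permutation p = 0.143, 35 splits). On the arrays with low poly-A controls the clones kept scores of -1.36 in parental, -1.37 in 16F8, -1.03 in 8G12, -1.21 in 17H5, -0.71 in 2C11 and -0.54 in 45G3. In the R132H, R132C and R172K clones the score rose against parental mainly through the epithelial list. Its mean changed by -0.545 in 2C11 to -1.336 in 2H1, and the mesenchymal mean by 0.067 in 45G3 to 0.314 in 2H1. The 2 means changed by -0.237 and -0.238 in 16F8, -0.226 and 0.117 in 8G12, and -0.136 and -0.055 in 17H5. The share of the 2 lists therefore depends on the reference. The epithelial and mesenchymal means were 8.943 and 7.651 in 16F8, 8.635 and 7.972 in 2C11, and 8.494 and 7.956 in 45G3. They were 8.319 and 7.992 in 47C2, 7.844 and 8.203 in 2H1, and 8.037 and 8.06 in 3A4.

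**Figure D2:**
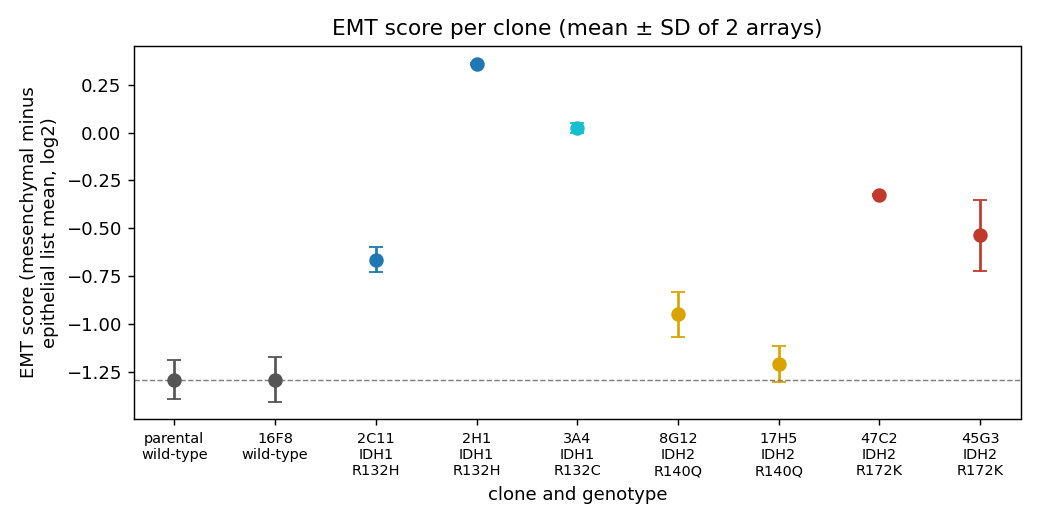
EMT score (y axis, log2; mesenchymal minus epithelial list mean) of the 9 clones (x axis), with the mean and SD of 2 arrays. The scores ran from -1.29 in parental and 16F8 to 0.36 in 2H1, with the R140Q clones at -0.95 and -1.21.

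The comparison of all 7 mutant clones with both wild-type clones asked which genes follow an expressed IDH mutation whatever its kind. The largest difference relative to its spread was in CCN2, a matricellular growth factor induced by YAP and TGF-beta, with signals of 144 against 58.4 and a log2 difference of 1.29 ± 0.21. LCN2, which encodes the siderophore-binding protein lipocalin, differed by -2.03 ± 0.45, and DRAXIN, an axon guidance protein, by 1.28 ± 0.27. RNF182, a ubiquitin ligase, differed by 1.02 ± 0.24, and HEG1, a transmembrane protein, by 0.97 ± 0.23. PTGER4, a prostaglandin E2 receptor, differed by 0.62, EFR3B by 1.02, CLN6 by 0.81, C9orf85 by -0.61 and the ribosomal protein gene RPL36 by -0.28. In each of these 10 genes all 7 mutant clones lay on 1 side of both wild-type clones. They were picked by their p in this same comparison, so this separation is no independent support. LCN2, PTGER4 and C9orf85 also set parental apart from 16F8. With 16F8 alone as the wild type they differed by -1.07, 0.34 and -0.36, CLN6 by 0.49, EFR3B by 0.65 and HEG1 by 0.65. The key genes differed by 0.94 ± 0.42 (ZEB1, 6 of 7 clones above both wild-type clones), -0.87 ± 0.36 (CDH1, 5 of 7 below), 1.05 ± 0.50 (VIM, 5 of 7 above), -0.33 ± 0.15 (EPCAM), 0.13 ± 0.20 (IDH1) and 0.38 ± 0.29 (IDH2). None of these passed limma's test: 0 of 12531 genes did (smallest adjusted p = 0.682), and 861 had an unadjusted p under 0.05 where 627 were expected. Without 16F8 the count was 80, and without parental 1.

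Epithelial markers as a group lay lower in the mutant clones, with a median of -0.47 over 34 tested members, although no member passed alone, over all genes or adjusted over the list alone. CLDN7, a tight junction claudin, differed by -1.15 ± 0.46 and CRB3, a polarity protein, by -0.65 ± 0.25. ESRP1, an epithelial splicing regulator, differed by -0.64 ± 0.24, and MARVELD2, of tricellular junctions, by -0.30 ± 0.12. The cell cycle list lay higher, with a median of 0.25 over 30 members, among them E2F1 (0.96 ± 0.27), which drives entry into S phase, and the replicative helicase genes MCM4 (0.70 ± 0.20) and MCM6 (0.37 ± 0.15). The amino acid and unfolded protein response list, targets of ATF4 and of endoplasmic reticulum stress, lay lower, with a median of -0.19 over 27 members. In camera these 3 lists had adjusted p = 5.19e-08, 7.05e-07 and 0.0295, but adjusted p = 0.866 for each with an estimated correlation, and in fry adjusted p = 0.732. The other 20 lists had adjusted p of 0.419 or more, including mesenchymal markers (median 0.06), miR-200 family targets (0.07) and EMT transcription factors (0.06). Without parental 7 lists passed. The cell cycle and amino acid response differences depend on the wild-type reference. Against the targeted wild-type clone alone, a reference chosen after seeing the data, cell cycle medians of single mutant clones ran from -0.24 to 0.07. Those of the amino acid response list ran from 0.02 to 0.81. E2F1, MCM4 and MCM6 were higher than in parental in every other clone, the targeted wild-type clone included.

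FN1, which encodes the matrix protein fibronectin, was higher than in both wild-type clones in 7 of 7 mutant clones, by 0.94 (exact permutation p = 0.0556), and ESRP1 and EPCAM were each below both in 6 of 7 (exact permutation p = 0.0833 for each). The exact tests of ZEB1 (p = 0.111), CDH1 (p = 0.139) and VIM (p = 0.194) over the same 36 splits did not pass either. These exact tests of single genes were not part of the plan made before the data were examined.

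Between IDH1-mutant and wild-type clones the smallest p was that of CPT1C, a brain-type relative of carnitine palmitoyltransferase, with signals of 40.6 against 179 and a log2 difference of -2.13 ± 0.25 (adjusted p = 0.0501). CEACAM1, a cell adhesion molecule, differed by 1.65 ± 0.25 and CEMIP2, a hyaluronidase of the cell surface, by 1.28 ± 0.20 (adjusted p = 0.133 for each). As groups, epithelial markers lay lower (median -0.71; CLDN7 -1.75 ± 0.37, S100A14 -3.98 ± 0.90), as did the amino acid response list (-0.39). Cell cycle genes (0.28), p53 targets (0.20), miR-200 family targets (0.12), NRF2 targets (0.16) and mesenchymal markers (0.14) lay higher. Their camera adjusted p ran from 3.96e-09 to 0.0353, but with an estimated correlation the adjusted p was 0.474 to 0.645. No member passed over all genes; adjusted over the list alone 21 epithelial markers were lower and 2 higher, and 2 p53 targets, 2 mesenchymal markers and 1 miR-200 target were higher. Against 16F8 the cell cycle medians were 0.07 in 2C11, 0.01 in 2H1 and -0.08 in 3A4. Those of the amino acid response list were 0.03, 0.10 and 0.22. Between IDH1-mutant and both wild-type clones no gene passed limma's test (0, with 1923 at an unadjusted p under 0.05). The count rose to 209 without 16F8 and 81 without 2C11, and was 1 without parental or 2H1; on arrays with the clone as a random block it was 380.

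Between IDH2-mutant and wild-type clones the smallest p-values were those of LCN2 (-2.35 ± 0.43, signals 36.1 against 232), CCN2 (1.24 ± 0.23, 137 against 58.4) and RPL6, a ribosomal protein gene (-0.27 ± 0.05), each with adjusted p = 0.89. The LCN2 difference depends on the reference, with -3.31 against parental alone and -1.38 against 16F8 alone. Epithelial markers (median -0.27, adjusted p = 1.58e-05) and cell cycle genes (0.21, adjusted p = 0.000119) were the lists past camera's threshold. Against 16F8 the cell cycle medians were -0.03 in 8G12, -0.24 in 17H5, -0.02 in 47C2 and 0.06 in 45G3. With both wild-type clones as the reference, each of the lists had adjusted p = 0.974 in camera with an estimated correlation. No gene passed limma's test (0, with 637 at an unadjusted p under 0.05), and without 16F8 29 did and without parental 1.

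Between the 2 groups of mutants, CPT1C was the 1 gene past the threshold, 1.82 ± 0.21 higher in the IDH2-mutant clones (144 against 40.6, adjusted p = 0.0418). All 4 IDH2-mutant clones, at 125 ± 17 to 183 ± 9.76, lay above all 3 IDH1-mutant clones, at 34.3 ± 8.06 in 2C11, 55.5 ± 2.69 in 2H1 and 32.2 ± 13.2 in 3A4; parental lay at 174 ± 33.3 and 16F8 at 184 ± 38.5. In the IDH2-mutant clones IDH1 differed by -0.40 ± 0.16 and IDH2 by 0.73 ± 0.18. ZEB1 differed by -0.76 ± 0.34, CDH1 by 0.57 ± 0.31, VIM by -0.90 ± 0.41 and EPCAM by 0.27 ± 0.12, none past limma's threshold. Among the lists, p53 targets lay lower in IDH2-mutant clones (median -0.25; TP53I3 -0.81 ± 0.14, MDM2 -0.31 ± 0.07; adjusted p = 2.17e-06, and 0.198 with an estimated correlation). Epithelial markers (0.41, 0.000103), cholesterol synthesis (0.24, 0.000516; its regulator SREBF2 0.95 ± 0.16) and fatty acid synthesis (0.25, 0.023) lay higher, each with adjusted p = 0.699 with an estimated correlation. The miR-200 family targets (-0.13, 0.00252) and mesenchymal markers (-0.11, 0.0117) lay lower, with adjusted p = 0.198 and 0.586 with an estimated correlation. NRF2 targets (-0.15), cell cycle genes (-0.08) and mitochondrial genes (-0.07) also passed camera, with adjusted p = 0.0123, 0.0384 and 0.0123. Their adjusted p was 0.295, 0.774 and 0.725 with an estimated correlation. No list member passed over all genes; adjusted over the list alone 9 p53 targets, 5 miR-200 targets and 5 NRF2 targets were lower, and 8 epithelial markers were higher and 3 lower. In 1650 genes the unadjusted p was under 0.05. The count of 1 became 0 without parental, 16F8, 3A4, 8G12, 17H5, 47C2 or 45G3, and 45 without 2C11; it was 0 without the filter or the variance trend and 102 with the clone as a random block.

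The 2 R132H clones, against both wild-type clones, had 4 genes past the threshold, 1 higher and 3 lower. MSX2, a homeobox transcription factor, rose by 1.47 ± 0.17 (671 against 238), and KRT23, a keratin, fell by 3.68 ± 0.39 (36 against 510). ACSM3, a medium-chain acyl-CoA synthetase, fell by 1.57 ± 0.18, and PDK1, the pyruvate dehydrogenase kinase, fell by 1.20 ± 0.13. Each of the 4 had adjusted p = 0.0418. The single R132C clone, 3A4, had 141 genes past it, 38 higher and 103 lower. The higher genes were 27% of these, but 40.9% with the offset at the median and 53.8% with an offset of 50, so the balance of directions rests on the offset. Its PMEPA1, a feedback inhibitor of TGF-beta signalling, rose by 5.07 ± 0.81, and TMEM158 by 3.28 ± 0.62. Where 1 of the signals lay under 12.3, the lowest array median, signals stand here and below in place of log2 changes, since the size of such a change rests on the offset. RGS4, a regulator of G protein signalling, was at 230 against 7.08, CLEC2B at 137 against 6.78 and MARCHF4 at 46.1 against 2.75. Lower in this clone were TTC22 (1.7 against 160), VHRT (6 against 218), UTS2, which encodes the peptide urotensin (4.1 against 160), SERPING1, the C1 inhibitor (0.5 against 35.4), and IFITM1, an interferon-induced protein (3.65 against 86.4). These tests rest on 1 clone and cannot separate the mutation from other properties of 3A4. The R132H count was 836 without 16F8, 76 without 2C11 and 0 without 2H1, 8G12, 17H5, 47C2 or 45G3. The R132C count was 877 without 16F8, 213 without 2H1, 22 without 8G12 or 17H5, 45 without 47C2 and 46 without 45G3.

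Between R140Q and wild-type clones the smallest p-values were those of IDH2 (1.00 ± 0.16, 250 against 125), CCN1, a matricellular relative of CCN2 (0.88 ± 0.15), and CCN2 (1.37 ± 0.26), with adjusted p = 0.999. Here 0 genes passed limma's test, 349 had an unadjusted p under 0.05, and the count was 16 without 16F8 and 1 without parental. For the R172K clones they were those of KRT23 (-2.73 ± 0.39, 74.1 against 510), C5orf24 (-0.79 ± 0.12) and LINC00992 (-1.31 ± 0.19), with adjusted p = 0.325. Again 0 genes passed limma's test, 1289 had an unadjusted p under 0.05, and 721 passed without 16F8 and 2 without parental. Between R172K and R140Q clones KRT23 differed by -2.41 ± 0.39 and C5orf24 by -0.71 ± 0.12, with adjusted p = 0.389 for each. As before, 0 genes passed limma's test, 851 had an unadjusted p under 0.05, and the count was 3 without parental or 16F8 and 1 without 2C11 or 2H1.

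Epithelial markers lay lower than in wild-type clones in the R132H (median -0.66, adjusted p = 2.64e-10), R132C (-0.84, 3.75e-08; 3A4 alone) and R172K clones (-0.55, 2.04e-11), and lower in R172K than in R140Q clones (-0.48, 7.33e-10). Over all genes 0, 4, 0 and 0 of 34 members passed, and adjusted over the list alone 17, 22, 13 and 7 were lower. The R140Q clones had a median of -0.10 and 0 members by either count. Cell cycle genes lay higher in the same 4 comparisons, with medians of 0.34, 0.19, 0.32 and 0.17. The amino acid response list lay lower in the R132H (-0.41) and R172K clones (-0.42), and p53 targets higher in the R132H (0.21) and R132C clones (0.11). With an estimated correlation the adjusted p of these lists was 0.508 or more. The cell cycle and amino acid response differences from wild-type clones depend on the reference. The targeted wild-type clone alone was a reference chosen after seeing the data. Against it, cell cycle medians ran from -0.08 to 0.07 in the single R132H, R132C and R172K clones. Those of the amino acid response list ran from 0.02 to 0.098 in the single R132H and R172K clones.

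Against parental, every clone differed in many genes, the wild-type clone 16F8 included. ANXA10, an annexin, was at 206 in parental and lower in 16F8 (1.35), 2C11 (3), 8G12 (1.15) and 17H5 (3.5). SPX, the peptide hormone spexin, was at 295 in parental and lower in 16F8 (4.25), 2C11 (9.35), 8G12 (7.15), 47C2 (3.3) and 45G3 (6.45). SPARC, a matricellular collagen-binding protein, rose in 16F8 (2.07 ± 0.24), 17H5 (2.30), 47C2 (3.17) and 45G3 (3.34), but fell in 3A4, by -1.49. In 16F8 MAT1A, a methionine adenosyltransferase, was higher (34 against 7.9), as was ZNF488 (44.8 against 8.6), and NRP1, the co-receptor neuropilin 1, was lower (2.35 against 91.9). In 2C11 TM4SF18 rose by 4.81 and SKIDA1 by 2.48, CYP1A1, a target of the aryl hydrocarbon receptor, was higher (24.7 against 3.05), and KRT23 fell by 4.10.

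In 2H1 PMEPA1 rose by 4.44, and LYZ, lysozyme (140 against 8.85), and the chemokine gene CCL26 (100 against 8.2) were higher. PCDH7, a protocadherin, was lower (11.7 against 1730), as were S100A14 (-5.79) and MAL2, of apical transport in epithelia (-5.67). In 3A4 PMEPA1 rose by 4.92, RGS4 (230 against 9.5) and CLEC2B (137 against 9.95) were higher, and SERPINA3 (1.95 against 157), TTC22 (1.7 against 108) and UTS2 (4.1 against 169) were lower. In 8G12 NRG1, a ligand of ERBB receptors, rose by 3.27 and APOBEC3G, a cytidine deaminase, by 3.06, KRTAP4-12 was higher (30.8 against 2), and SLC40A1, the iron exporter ferroportin, was lower (0.85 against 39.8). In 17H5 SYTL5 (72.4 against 12) and LDB2 (23.2 against 3) were higher, and GARIN5A (2.8 against 85.3) and SLC40A1 (0.6 against 39.8) were lower. In 47C2 SNAP25, a SNARE protein (68.2 against 6.05), and PAQR9 (27.2 against 1.4) were higher, and GALNT3, a mucin-type glycosyltransferase (8.35 against 292), and the kinase SYK (1.75 against 55.8) were lower. In 45G3 the transcription factor FOXQ1 rose by 2.77 and SKIDA1 by 2.52, SERPINA3 was lower (9.45 against 157), and IL20RB, a cytokine receptor chain, fell by 3.63. All of these passed the threshold.

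The genes past the threshold against parental numbered 2758 in 16F8 (1560 higher and 1198 lower), 3234 in 2C11 (1676 and 1558), 3869 in 2H1 (1836 and 2033), 4659 in 3A4 (2205 and 2454), 2310 in 8G12 (1429 and 881), 1484 in 17H5 (862 and 622), 3505 in 47C2 (1779 and 1726) and 3740 in 45G3 (1900 and 1840). With 16F8 in place of parental, a reference chosen after seeing the data, the counts were 282 in 2C11 (123 and 159), 2061 in 2H1 (806 and 1255), 3298 in 3A4 (1298 and 2000), 79 in 8G12 (66 and 13), 1069 in 17H5 (552 and 517), 803 in 47C2 (287 and 516) and 268 in 45G3 (115 and 153). Of these, 197, 1233, 2029, 33, 162, 464 and 187 passed in the same direction against both references. The higher genes were 58.1% of those in 17H5 against parental, and 49.8% after quantile normalization. Leaving out 1 array changed some counts against parental by over 1.5 times: 17H5 had 902 without parental 1, 857 without parental 2, 940 without its replicate 1 and 506 without its replicate 2. 8G12 had 1250 without parental 2 and 1332 without its replicate 1. Likewise 16F8 had 1568 without parental 2 and 1692 without its replicate 2, 2C11 had 2122 without its replicate 2, 2H1 2545 without its replicate 1, and 47C2 2036 and 1991 without its replicates 1 and 2. Without the 4 arrays with high poly-A controls the counts were 1712 in 16F8, 2037 in 2C11 and 1508 in 8G12, and with their group as a term 17H5 had 2234.

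**Figure D3:**
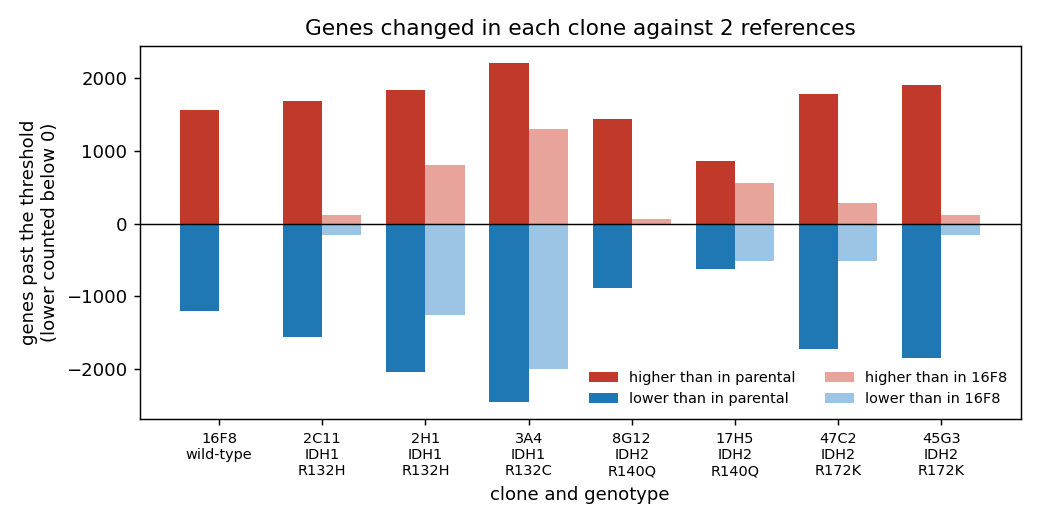
Number of genes past the threshold (y axis; higher above 0, lower below 0) for each clone (x axis), against parental and against 16F8. 8G12 had 2310 genes against parental and 79 against 16F8, and 3A4 had 4659 and 3298.

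Epithelial markers fell as a group in all 8 clones relative to parental. Of 34 tested members, 25 were lower and 1 higher in 2H1 (median -1.02), 25 and 1 in 3A4 (-0.95), 23 and 0 in 47C2 (-0.62), 21 and 0 in 45G3 (-0.63) and 19 and 0 in 2C11 (-0.55), against 8 and 0 in 16F8 (-0.23), 8 and 0 in 8G12 (-0.16) and 6 and 1 in 17H5 (-0.15). In the same order, adjusted over the list alone the lower members numbered 26, 26, 27, 23, 20, 9, 8 and 7. S100A14, an epithelial calcium-binding protein, had changes of -5.79 in 2H1, -4.67 in 3A4, -3.16 in 47C2, -2.60 in 2C11, -2.36 in 45G3 and -0.76 in 16F8. RAB25, a GTPase of epithelial recycling, had changes of -3.71 in 2H1, -2.66 in 3A4 and -1.52 in 47C2, and AP1M2, an epithelial sorting adaptor, of -3.25 in 2H1 and -2.36 in 47C2. The camera adjusted p ran from 4.23e-14 in 2H1 to 0.0159 in 17H5. With an estimated correlation the adjusted p was 0.00229 in 2H1, 3A4 and 47C2, 0.00251 in 45G3, 0.0067 in 2C11, 0.0444 in 8G12 and 0.0476 in 16F8, but 0.105 in 17H5. Against 16F8 the list fell in 2C11 (6 lower), 2H1 (22 lower and 3 higher), 3A4 (25 and 3), 47C2 (15) and 45G3 (10), with adjusted p = 0.0167, 0.0018, 0.0036, 0.0018 and 0.0018 with an estimated correlation, and had no member past the threshold in 8G12 (median 0.01, adjusted p = 0.947) or 17H5 (0.12, adjusted p = 0.182).

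Mesenchymal markers moved both ways. Against parental 8 of 25 were higher and 2 lower in 2H1, 8 and 4 in 3A4, 6 and 4 in 2C11, 5 and 6 in 45G3, 5 and 3 in 8G12, 4 and 4 in 47C2 and 3 and 4 in 17H5, with the list not past camera's threshold in any of these. In 16F8 it passed, with 2 higher and 5 lower (median -0.25, adjusted p = 0.0295, and 0.314 with an estimated correlation). FN1 rose by 1.66 in 2H1 and 1.54 in 3A4. NT5E, the ecto-nucleotidase CD73, fell in 7 clones, with changes of -1.59 in 16F8, -1.63 in 2C11, -1.68 in 2H1, -1.65 in 8G12 and -1.37 in 45G3. Against 16F8 the list lay higher in 2C11, 2H1 (9 higher, median 0.27), 3A4, 8G12, 47C2 and 45G3, with camera adjusted p of 3.93e-05 in 2H1 to 0.0301 in 45G3, and 0.0665 to 0.345 with an estimated correlation.

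Cell cycle genes rose as a group in all 8 clones relative to parental. Of 30 tested, 20 were higher in 16F8, 23 in 2C11, 22 in 2H1, 19 in 3A4, 17 in 8G12, 13 in 17H5, 20 in 47C2 and 20 in 45G3, none were lower, and the medians ran from 0.31 in 17H5 to 0.58 in 2C11. In the same order, adjusted over the list alone the higher members numbered 24, 26, 24, 19, 21, 18, 20 and 24. GINS2, part of the replicative helicase, rose by 1.25 ± 0.13 in 16F8, 1.23 in 2C11, 1.34 in 45G3 and 0.81 in 17H5. CCNE2, an S phase cyclin, rose by 1.21 ± 0.12 in 16F8 and 1.48 in 2H1, and PCNA, the replication clamp, by 0.86 in 16F8 and 1.13 in 2C11. The camera adjusted p ran from 1.83e-12 in 2C11 to 5.4e-06 in 17H5. With an estimated correlation the adjusted p was 0.0476 in 2C11 and 0.0538 to 0.168 in the other 7 clones. Against 16F8 the medians ran from -0.24 in 17H5 to 0.07 in 2C11, and the list passed camera in 17H5 alone. There 5 of 30 genes were lower (camera adjusted p = 4.25e-05, and 0.224 with an estimated correlation).

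The amino acid and unfolded protein response list fell in every clone except 17H5. Of 27 tested, 22 were lower in 16F8, 23 in 2C11, 21 in 2H1, 21 in 3A4, 13 in 8G12, 21 in 47C2 and 22 in 45G3, and 1, 0, 1, 2, 0, 2 and 1 were higher. The medians ran from -1.09 in 2C11 to -0.42 in 8G12, and adjusted over the list alone the lower members numbered 23, 23, 22, 21, 16, 22 and 25. TRIB3, a pseudokinase induced by ATF4, had changes of -2.50 in 16F8, -2.54 in 45G3, -2.97 in 2H1 and -1.56 in 8G12, and ASNS, asparagine synthetase, of -1.51 in 16F8, -1.73 in 2C11 and -1.93 in 2H1. SLC7A11, the cystine transporter, had -2.32 in 16F8 and -2.08 in 45G3, and DDIT3, the stress factor CHOP, -2.17 in 16F8 and -2.19 in 47C2. In 17H5 DDIT3 rose by 1.03 and the serine synthesis gene PHGDH fell by 0.89. The camera adjusted p ran from 2.04e-17 in 16F8 to 1.58e-07 in 3A4; with an estimated correlation the adjusted p was 0.0403 in 16F8, 0.0476 in 2C11, 0.0538 in 45G3, 0.061 in 47C2, 0.0774 in 2H1, 0.125 in 8G12 and 0.162 in 3A4.

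Cholesterol synthesis genes rose relative to parental in 16F8 (13 of 19 tested higher, median 0.55), 8G12 (13, 0.58), 45G3 (12 higher and 1 lower, 0.45), 17H5 (8, 0.27), 47C2 (7, 0.27) and 2C11 (7 higher and 1 lower, 0.24). In the same order, adjusted over the list alone the higher members numbered 14, 14, 12, 9, 7 and 8. ACAT2, acetyl-CoA acetyltransferase, rose by 1.34 in 16F8, 1.51 in 2C11, 1.28 in 8G12 and 1.55 in 45G3. INSIG1, which retains the sterol sensor in the endoplasmic reticulum, rose by 1.11 in 16F8 and 0.94 in 8G12, and LSS, lanosterol synthase, by 0.89 in 16F8 and 1.04 in 8G12. The camera adjusted p ran from 1.52e-07 in 16F8 to 0.0191 in 47C2; with an estimated correlation the adjusted p was 0.0162 in 16F8 and 8G12, 0.0377 in 17H5, 0.0517 in 45G3, 0.145 in 2C11 and 0.161 in 47C2.

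**Figure D4:**
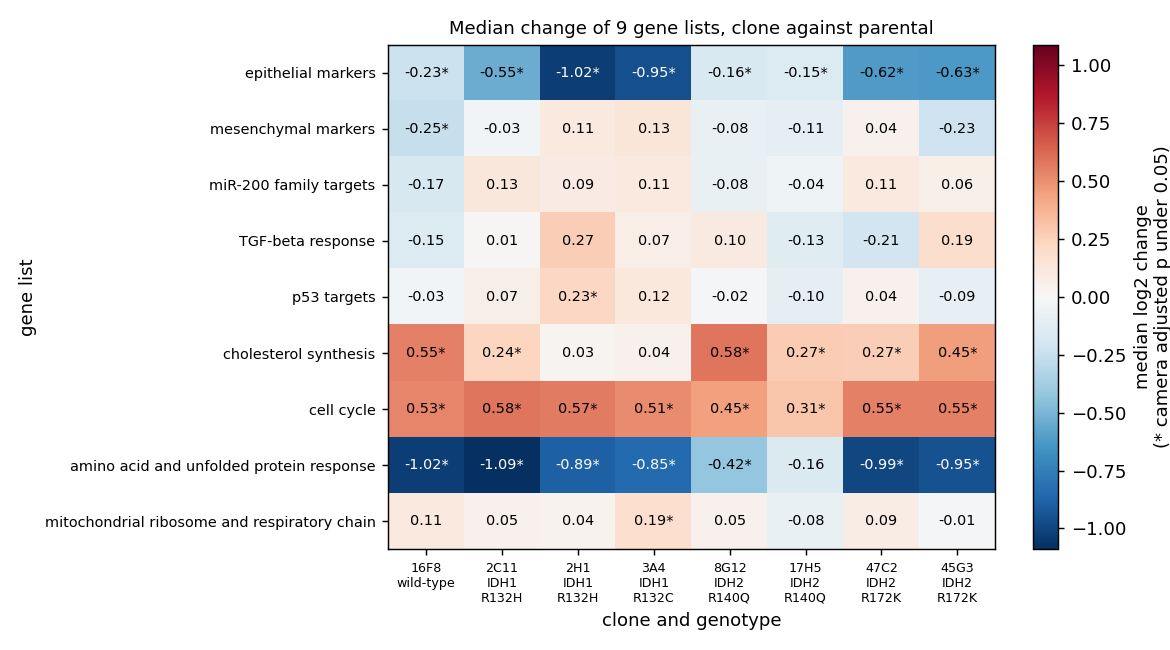
Median log2 change against parental (colour) of 9 gene lists (y axis) in 8 clones (x axis), with * for a camera adjusted p under 0.05. Cell cycle medians ran from 0.31 to 0.58 and epithelial medians from -1.02 to -0.15.

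Smaller groups passed in single clones. Genes of DNA methylation and Polycomb machinery rose in 2C11 (7 of 20 higher and 2 lower, median 0.30; the helicase HELLS 1.16, UHRF1 0.84) and 2H1 (8 and 1, 0.21), with camera adjusted p = 0.0247 and 0.0335, and 0.157 and 0.17 with an estimated correlation. HELLS and UHRF1 were higher than in parental in all 8 clones, 16F8 included. With 16F8 as the reference the list did not pass in 2C11 (median 0.04, camera adjusted p = 0.286) or 2H1 (-0.05, 0.566). In 2H1 8 of 21 p53 targets were higher and 2 lower (median 0.23; SESN1 1.42, TIGAR 1.04; adjusted p = 0.0273, and 0.207 with an estimated correlation). In 17H5 6 of 24 hypoxia targets were higher (0.18; the glucose transporter gene SLC2A3 0.79; adjusted p = 0.0385, and 0.511 with an estimated correlation). There 4 of 13 fatty acid synthesis genes were higher and 1 lower (0.30; FASN 1.20; adjusted p = 0.0291, and 0.687 with an estimated correlation). In 3A4 7 of 27 mitochondrial genes were higher (0.19; NDUFA9 0.67, SDHA 0.68; adjusted p = 0.0117, and 0.74 with an estimated correlation). Of the 184 pairs of a list and a clone, 36 passed in camera, 13 of them also with an estimated correlation. The other 13 lists passed in no clone (smallest adjusted p = 0.0771), among them EMT transcription factors, miR-200 family targets, the TGF-beta response, 2-oxoglutarate-dependent dioxygenases and the fibroblast and haematopoietic markers, of which only 2 and 4 genes were tested. Against 16F8 miR-200 family targets passed as higher in 2C11, 2H1, 3A4 and 45G3 (camera adjusted p = 0.000954, 0.00158, 0.0253 and 0.0301), and 0.345, 0.369, 0.49 and 0.49 with an estimated correlation. The TGF-beta response passed as higher in 2C11, 2H1, 8G12 and 45G3 (adjusted p = 0.0305, 0.00112, 0.0302 and 0.000191), and 0.345, 0.133, 0.345 and 0.1 with an estimated correlation. The medians of called lists, against parental or 16F8, gave 312 values in total under 4 other offsets or scalings, and 0 of these changed sign.

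In 487 genes parental lay apart from all 8 other clones, 216 of them higher in parental and 271 lower. The same count was 378 for 3A4, 78 for 2H1, 42 for 17H5, 15 for 47C2, 9 for 16F8, 5 for 2C11, 5 for 8G12 and 0 for 45G3. Arrays simulated with no effect gave 0, but without differences between clones they set no scale for clones that do differ. Of the genes tested in each list, 12 of 30 cell cycle genes and 2 of 19 cholesterol genes lay lowest in parental, and 6 of 27 amino acid response genes and 3 of 34 epithelial markers highest; most of the 487 genes are in no list and are not described here. All 8 comparisons share the same 2 parental arrays. Of 184 pairs of a clone and a chromosome, from 1 to 22 and X, 0 passed in limma's camera, with a smallest adjusted p of 0.993.

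**Figure D5:**
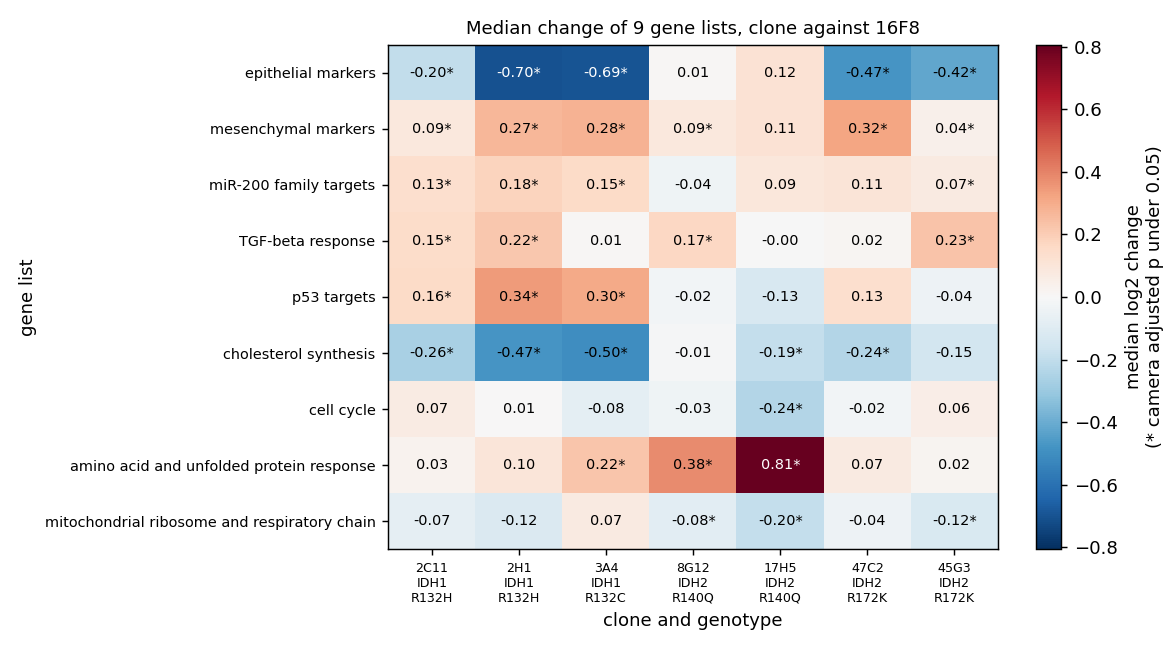
Median log2 change against 16F8 (colour) of 9 gene lists (y axis) in 7 clones (x axis), with * for a camera adjusted p under 0.05. Epithelial medians ran from -0.70 in 2H1 to 0.12 in 17H5, and the amino acid response list reached 0.81 in 17H5.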

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

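The tests of the EMT score by genotype, the leaving out of arrays by their poly-A controls and the comparisons with 16F8 were chosen only after the results were seen; the counts of genes against parental with the poly-A term and after quantile normalization had also been seen before the tests on parental were run.

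CPT1C was 1.82 higher on the log2 scale in the IDH2-mutant than in the IDH1-mutant clones, the 1 gene that differed between these groups. IDH1 differed by -0.40 between the same groups (exact permutation p = 0.0286, the smallest that 35 splits allow), 1 of 18 genes tested in this way, so chance over 18 tests is not excluded. The EMT score and named genes were tested for a lone high or low clone among the 7 mutant or the 4 IDH2-mutant clones. In these 28 tests 0 clones stood apart. Many of the genes had been named for a small p between the same groups, which favours a small spread within a group. The 0 is therefore no evidence against a deviating clone.

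Parental lay apart from all 8 clones in 487 genes, with low cell cycle and high amino acid response genes. A batch of arrays seen in the poly-A controls is argued against as the whole cause by the design: parental, 16F8, 2C11 and 8G12 each held 1 such array. With that batch as a term 457 of the 487 genes still separated parental, a result that this balance made likely. The scaling of each array is argued against as the whole cause too, since 415 of the genes still separated parental after quantile normalization. A single deviating culture is argued against for the cell cycle genes, whose list mean was 9.26 and 9.23 in the 2 parental arrays, both under the lowest of the 16 other arrays (9.59). It is argued against for the amino acid response list outside 17H5 as well: its mean was 9.96 and 10.07 in the parental arrays and at most 9.59 in the 14 arrays of the other 7 clones, while 17H5, in which the list did not pass, reached 9.95. What stays open is a biological difference between a line that went through no targeting and cloning and 8 that did, changes of the genome in the founding cells included, or a difference in how the parental cultures were grown; each may give a part of the pattern, which need not have 1 cause, and neither was tested. 16F8, wild-type at the mRNA level per the labels, is among the 8, so the pattern is not confined to mutant clones.

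The EMT score was low in both R140Q clones and higher in the other 5 mutant clones. The poly-A batch is argued against, because on the arrays with low controls the lowest of the 5 others still lay 0.32 above the higher R140Q clone, beyond the pooled replicate SD of 0.0982. Clone-to-clone variation unrelated to the mutation stays open: 33 of the 105 ways to group the 7 mutant clones (31.4%) put clones of a group at least as close in score as the real genotypes did. An effect of the kind of mutation may exist as well and could not be separated from it with 1 or 2 clones per mutation.

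For the single gene between IDH2- and IDH1-mutant clones, chance cannot be excluded: 3 of the 35 splits of the 7 mutant clones, the real one included, gave at least 1 gene, and the highest of the others gave 20. CPT1C is read by 1 probe set, with 0 others on the array to compare, so a fault of that probe set and a lower transcript level cannot be told apart here.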

How the results depend on the processing

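The offset of 50, the alternatives on the 4 arrays with high poly-A controls and 16F8 as the reference for single clones were chosen only after the data were seen; the cause of the differences below was not tested unless stated. Under all settings run the mutant clones kept the higher EMT score, by 0.62 to 0.99 (exact permutation p = 0.0556 to 0.25), and 0 of the chromosome shifts passed. Settings that leave out a clone have fewer splits and a higher smallest possible p, most of all without a wild-type clone. Their p-values are therefore not on 1 scale with the others. The gene lists by clone that passed numbered 31 to 42 against 36. Signal over background limits dim genes: 15.4% of values lay under 1. The 148 results for single genes gave 1835 values under the other settings, of which 1674 kept direction and side of the threshold, 76 no longer passed, 54 newly passed and 31 reversed; of 2186 values with 1 array or clone left out, 2067 kept both, 91 no longer passed, 18 newly passed and 10 reversed. The EMT score has no variance model or block, and camera takes no random block for mutant against wild-type lists, so these were not run. Counts follow in the order IDH1 against wild-type (main count 0), IDH2 against wild-type (0), IDH2 against IDH1 (1), R132H (4), R132C (141), R140Q (0), R172K against wild-type (0) and R172K against R140Q (0), naming those that moved. With the clone as a random block on arrays, which raises the number of samples, they were 380, 1, 102, 382, 1085, R172K 123 and R172K against R140Q 80. With the replicate number as a further block in that fit on the arrays they were 323, 1, 84, 361, 1010, 67 and 75, and with the poly-A group in its place 263, 1, 98, 342, 849, 46 and 67. With parental alone as the wild type mutant against wild-type had 80, and the others 209, 29, R132H 836, R132C 877, R140Q 16 and R172K 721; with 16F8 alone mutant against wild-type had 1, IDH1 1, IDH2 1, R140Q 1 and R172K 2, and 7 lists passed in place of 3. The offset at the median gave IDH1 1 and R132H 7, quantile normalization IDH1 1, the probe set of highest variance IDH1 1, R132H 0 and 5 lists, and no filter 0 for IDH2 against IDH1. Without the variance trend the counts were 0 for IDH2 against IDH1, 1 for R132H and 80 for R132C, and with the offset of 50 IDH1 1, R132H 0 and R132C 91. Without the 4 high poly-A arrays they were 2 for IDH2 against IDH1, 8 for R132H and 61 for R132C, and for clones against parental 1712 in 16F8, 2037 in 2C11 and 1508 in 8G12; with their group as a block 17H5 had 2234. Against 16F8 the clones had 282 (2C11), 2061 (2H1), 79 (8G12), 803 (47C2) and 268 (45G3).

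Leaving out 1 clone gave 0 to 80 genes for mutant against wild-type, 2 to 7 lists, 0 to 209 for IDH1, 0 to 29 for IDH2, 0 to 45 for IDH2 against IDH1, 0 to 836 for R132H, 22 to 877 for R132C, 0 to 16 for R140Q, 0 to 721 for R172K, 0 to 3 for R172K against R140Q and 0.68 to 0.94 for the EMT score. Leaving out 1 array gave 1568 to 3011 genes in 16F8, 2122 to 3465 in 2C11, 2545 to 4050 in 2H1, 3131 to 4870 in 3A4, 1250 to 2562 in 8G12, 506 to 1722 in 17H5, 1991 to 3750 in 47C2, 2521 to 3788 in 45G3, 32 to 42 lists and 0 chromosomes. Where a clone keeps 1 array, that array is assumed to vary like the others.

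Reversed log2 changes were these. With the probe set of highest variance IDH2 was 0.98 in 16F8, 0.52 in 2H1 and 0.88 in 3A4, ZEB1 -0.36 in 2C11 and -0.49 in 8G12, and IDH1 0.31 in 3A4 and 0.52 in 17H5. With parental alone, or without 16F8, IDH1 was -0.23 in mutant against wild-type clones. With the poly-A block IDH2 was 0.01 in 2H1 and 0.08 in 3A4, and without those arrays 0.24 in 16F8, 0.15 in 2H1 and 0.22 in 3A4, with ZEB1 -0.12 in 8G12. With 16F8 as the reference ANXA10 was 0.66 in 2C11, 0.02 in 8G12 and 0.75 in 17H5, SPX 0.84 in 2C11, 0.54 in 8G12 and 0.40 in 45G3, IDH1 0.48 in 3A4, 0.33 in 8G12, 0.39 in 17H5, 0.25 in 47C2 and 0.31 in 45G3, CDH1 0.02 in 8G12 and 0.35 in 17H5, VIM 0.63 in 8G12 and 0.09 in 17H5, EPCAM 0.02 in 17H5, and ZEB1 0.10 in 17H5. With 1 array left out, changes that reversed ran from -0.31 to 0.26 for IDH2 in 16F8, -0.25 to 0.32 in 2C11, -0.45 to 0.18 in 2H1 and -0.35 to 0.22 in 3A4. In 8G12 they ran from -0.09 to 0.23 for ZEB1 and -0.40 to 0.04 for VIM, and with 1 clone left out from -0.23 to 0.49 for IDH1 in mutant against wild-type clones.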

Other observations

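The comparisons with 16F8 below were chosen only after the data were seen. Against this wild-type clone, cholesterol synthesis genes were lower in 5 clones: 13 of 19 fell in 2H1 (median -0.47), 13 in 3A4 (-0.50), 6 in 47C2 (-0.24), 2 in 2C11 (-0.26) and 4 in 17H5 (-0.19). The adjusted p in camera with an estimated correlation was 0.0153, 0.0167, 0.0384, 0.0384 and 0.22. The direction depends on the wild-type reference: 16F8 itself had a median of 0.55 against parental, and against parental the list was higher in 47C2 (0.27), 2C11 (0.24) and 17H5 (0.27). SREBF2, the regulator of the pathway, had log2 changes of -1.13 ± 0.14 in 2H1, -1.13 ± 0.14 in 3A4 and -0.57 ± 0.14 in 2C11. STARD4, a sterol carrier, had -1.04 in 2H1 and -1.40 in 3A4, and SQLE, squalene epoxidase, -0.93 in 3A4. The p53 target list rose in 2H1 (7 of 21, median 0.34), 3A4 (10 of 21, 0.30) and 2C11 (1 of 21, 0.16), with adjusted p = 0.0273, 0.0491 and 0.133 with an estimated correlation. TP53I3 rose by 0.85 ± 0.13 in 2H1 and 0.91 ± 0.13 in 3A4, and TIGAR, a regulator of glycolysis, by 0.67 and 0.79.

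The amino acid and unfolded protein response list rose against 16F8 in both R140Q clones, with 8 of 27 members higher in 8G12 (median 0.38) and 15 in 17H5 (0.81), and an adjusted p of 0.0384 in each with an estimated correlation. Against parental the same list was lower in 8G12 (13 of 27 lower, median -0.42) and in 16F8 itself (-1.02), and did not pass in 17H5 (-0.16). CHAC1, which degrades glutathione, rose by 3.49 ± 0.27 in 8G12 and 4.41 ± 0.27 in 17H5, DDIT3 by 1.93 ± 0.17 and 3.21 ± 0.17, and ATF3, a stress-induced transcription factor, by 1.33 ± 0.13 and 2.06 ± 0.13. In the 5 other mutant clones the medians of this list were 0.03 in 2C11, 0.10 in 2H1, 0.22 in 3A4, 0.07 in 47C2 and 0.02 in 45G3, and only 3A4 passed in camera (adjusted p = 0.00484, and 0.475 with an estimated correlation). Of 161 pairs of a list and a clone, 42 passed against 16F8, 13 of them also with an estimated correlation.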
